A study of Mus musculus with 4 samples.

How the data were processed

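The series measured RNA in single cells of tissue labelled KPC tumour. KPC names an engineered mouse line that develops pancreatic tumours. There were 4 libraries: 2 from tissue labelled Normal, with genotype WT, and 2 from tissue labelled Cstf2_KD. Per the labels, the tissue was digested with collagenases and DNase, sieved, freed of red blood cells and loaded on the 10x Genomics droplet system. How the knockdown was made, and whether the 2 libraries of a group came from separate animals, is not given in the sources used here. The p-values therefore measure the spread between libraries, which may be technical.

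The deposited matrices hold counts, namely raw UMI counts per gene and droplet barcode, with no cell filter and no normalisation. Per the file headers, the authors made them with Cell Ranger 4. The submitters' processing notes also name the mm10 build and Seurat 4.3.0, and Seurat leaves no trace in these matrices. Of the 32285 gene identifiers, 32158 were found in the GRCm38 annotation, which gave the positions and chromosomes. The symbols Cxcl11, Mx1, Mx2 and Ca9 were not among the feature names, so no value is given for them.

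Barcodes with at least 500 UMIs, at least 300 detected genes and at most 20% mitochondrial UMIs were kept as cells. Doublet scores came from the Scrublet method in scanpy 1.11.5, run per library with an expected rate of 0.06. Its automatic threshold marked 0 or 1 barcodes per library, so the 6% of barcodes with the highest scores were removed from each library instead, a change made after the data were seen. Counts were scaled to 10000 UMIs per cell and log-transformed. The 2000 most variable genes, chosen with the library as batch key, gave 30 principal components and a graph of 15 neighbours. Leiden clustering (leidenalg 0.10.2, resolution 1.0) was run on all cells together without integration. Each cluster was named from fixed marker lists, as "T-like" for example, and stayed unnamed when markers of another type were as frequent among its 10 leading genes. The details of that naming rule were set once the clusters had been seen.

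UMIs of each class were summed per library, and a class was tested only with at least 20 cells in every library. The groups were compared with the edgeR 4.0.16 quasi-likelihood test (filterByExpr, TMM, robust fit) on 2 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over the genes tested in a class, with a threshold of 0.05. CPM values are TMM-normalised unless given as raw, and each log2 fold change is Cstf2_KD over Normal with its standard error. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, where at least 3 members were tested, and adjusted over the lists within a class. Camera with an estimated correlation and fry were run beside it. Shares of cells were compared with the edgeR test on numbers of cells and with a two-sided exact permutation test, whose smallest p with 2 against 2 libraries is 0.333. For T cell subsets each cell was thinned to 1000 UMIs, and T-like cells with fewer were left out (58 to 110 per library). The difference between the epithelial-like and the macrophage-or-monocyte-like change was tested as an interaction with library as a block. A correlation across samples is not reported, as there are only 4 libraries.

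Groups, tests, marker lists, 30 gene lists and the rule for named genes were fixed before the data were examined. The rule took Cstf2, its retrocopy Cstf2t, Cxcl9 and Cxcl10 in each class. For the 3 tested classes with the most cells it took up to 10 genes in each direction, and for other classes up to 4. These had an adjusted p under 0.05, a log2 fold change of at least 1 in size, an average log2 CPM of at least 5, and both Cstf2_KD libraries on the same side of both Normal libraries. Predicted genes and markers of another class were left out. Where none passed, the 3 with the lowest p in each direction were taken. Up to 4 members of each list that passed were added, and Cd8a, Cd8b1, Cd4, Foxp3, Ifng, Gzmb and Pdcd1 in T-like cells. From these the text gives examples.

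Alternatives were stricter cells (1000 UMIs and 500 genes), at most 10% mitochondrial UMIs, doublets kept, Leiden resolution 2.0, classes from per-cell marker scores, TMM on the class table, DESeq2 size factors, no gene filter, the DESeq2 1.42.0 Wald test, a replicate block and leaving out each library. In another alternative, genes were left out where free RNA, taken from droplets under 100 UMIs and scaled to markers of other classes, made up over 10% of the counts in either group. That scaling can also count real expression as free RNA. Further alternatives were chosen after seeing the data: clusters with low Xist together, clusters 6 and 12 each alone, macrophage-or-monocyte-like cells without a T cell marker UMI, and a block with crossed pairs.

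The tests were checked on simulated data, with the common dispersion and depth of each class for the gene tests. Every gene of a class was given the same dispersion, while real genes differ in theirs. Recovery at the real spread of single genes was therefore not tested and may be lower. Of 100 genes changed 4-fold, edgeR recovered 93 in T-like, 96 in macrophage-or-monocyte-like, 93 in epithelial-like and 54 in neutrophil-like cells. At 2-fold these numbers were 61, 64, 27 and 8. False calls were 1 to 14 per class. A simulated 4-fold change of a class share was recovered in 97 of 100 tables of 8 classes, and 11 times an unchanged class was called. That simulation set a dispersion below the 0.229 estimated from the real class shares. Recovery of share changes at the real spread was therefore not tested. The replicates of a group differed beyond sampling noise in every class, with chi-square per degree of freedom between 3.71 in NK-like cells and 310 for all cells summed. Exact binomial and Poisson intervals (95%) cover counting error only. The remaining software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, matplotlib 3.10.9 and R 4.3.3.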

Results

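Single-cell RNA was profiled in tissue labelled KPC tumour to follow what a knockdown of Cstf2 does to the tumour microenvironment. CSTF2 is a subunit of the cleavage stimulation factor, which takes part in forming the 3' ends of messenger RNA. There were 2 libraries labelled Normal and 2 labelled Cstf2_KD. Total UMIs were 68895424 in Normal replicate 1, 103536237 in Normal replicate 2, 104793529 in Cstf2_KD replicate 1 and 133119848 in Cstf2_KD replicate 2. The cells kept numbered 10071, 10347, 12257 and 14545 in that order, with median depths of 3002, 4788, 4387 and 3863 UMIs. Droplets under 100 UMIs held 6.17% and 3.75% of all UMIs in the Normal libraries, and 2.15% and 2.08% in the Cstf2_KD libraries.

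Clustering gave T-like, macrophage-or-monocyte-like, neutrophil-like, NK-like, dendritic-like, mast-or-basophil-like, epithelial-like, fibroblast-like, endothelial-like and pericyte-like cells. Clusters 3, 9, 12 and 19 carried no clear name and held 10.9% and 14.4% of the Normal cells against 17.5% and 36.7% of the Cstf2_KD cells. Among them, cluster 12 held 1.52% and 2.32% of the Normal cells and 3.05% and 12.2% of the Cstf2_KD cells. Its leading genes included Spp1, Grem1 and Sox9. The epithelial-like class, 731, 908, 206 and 530 cells, drew on 3 clusters. Cluster 6 supplied 717, 827, 81 and 305 of these cells, cluster 16 supplied 14, 49, 78 and 221, and cluster 22 supplied 0, 32, 47 and 4. Cluster 6 thus held most of the class in Normal tissue, while clusters 6 and 16 together held most of it in Cstf2_KD tissue.

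Cstf2 RNA (ENSMUSG00000031256) was lower in the Cstf2_KD libraries, and in epithelial-like cells this passed the test. In all kept cells raw Cstf2 was 17.6 CPM (95% Poisson interval 16.5 to 18.7) in Normal replicate 1 and 16.5 (15.6 to 17.4) in Normal replicate 2. It was 11.7 (11.0 to 12.5) in Cstf2_KD replicate 1 and 8.68 (8.14 to 9.25) in Cstf2_KD replicate 2. In epithelial-like cells raw Cstf2 was 18.3 and 17.8 CPM in the Normal libraries and 10.2 and 7.96 in the Cstf2_KD libraries. There it fell by 1.07 ± 0.16 on the log2 scale (SE, n = 2 libraries per group, adjusted p = 0.00351). The unnamed cluster 12 had 27.8 and 18.9 raw CPM in Normal and 2.90 and 3.54 in Cstf2_KD (log2 fold change -2.61 ± 0.24, adjusted p = 1.25e-04, a comparison added after the data were seen). In macrophage-or-monocyte-like cells the change was -0.73 ± 0.21 and did not pass (adjusted p = 0.162), and in T-like cells it was -0.19 ± 0.15 (adjusted p = 0.592). All cells summed gave -0.64 ± 0.19 (adjusted p = 0.587). Cstf2t (ENSMUSG00000053536), an intron-poor relative of Cstf2 with which reads could be shared, also fell in epithelial-like cells, by 0.93 ± 0.19 (adjusted p = 0.0102). Without Normal replicate 1 the Cstf2t change was -0.69 with an adjusted p of 0.0562. With genes set aside for free RNA, Cstf2 was not tested in epithelial-like cells, since free RNA was put at 10.4% of its Cstf2_KD counts. On GRCm38 Cstf2 lies on the plus strand of chromosome X from 134059187 to 134086819, and Cstf2t on the plus strand of chromosome 19 from 31082837 to 31087069.

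**Figure D1:**
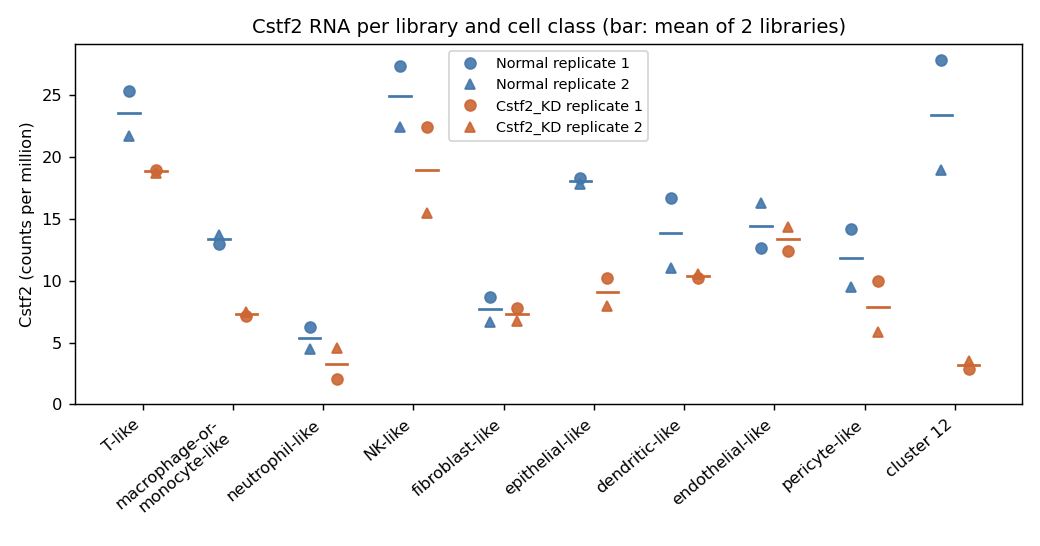
Raw Cstf2 CPM (y axis) for each cell class (x axis), with 1 point per library and bars at the mean of 2 libraries. Epithelial-like cells sit at 18.3 and 17.8 CPM in Normal and 10.2 and 7.96 CPM in Cstf2_KD.

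The question whether the cellular makeup of the tumour differed was addressed with the share of each class. Epithelial-like cells made up 8.02% ± 1.07 of the Normal cells (SD, n = 2) and 2.66% ± 1.39 of the Cstf2_KD cells, with log2 fold change -1.59 ± 0.57 and adjusted p = 0.325 by edgeR. Macrophage-or-monocyte-like cells made up 21.2% ± 1.85 and 13.1% ± 1.38 (log2 fold change -0.69 ± 0.45, adjusted p = 0.674). T-like cells, 28.2% ± 4.79 and 30.5% ± 5.26, and NK-like cells, 5.70% ± 3.96 and 7.74% ± 2.68, differed by less than the spread between replicates. Neutrophil-like cells were 14.0% and 10.3% in Normal but 15.1% and 1.88% in the Cstf2_KD replicates, so Cstf2_KD replicate 2 stood apart. Without that library their log2 fold change was 0.31 rather than -0.52. No class passed the edgeR test, 1 class had an unadjusted p under 0.05, and in the exact permutation test 2 of the 6 splits of the libraries gave a difference as large for epithelial-like and for macrophage-or-monocyte-like cells, the fewest that 2 against 2 libraries allow. The epithelial-like share depended on which clusters were counted. With clusters 6, 12 and 16 together, a grouping added after the data were seen, the shares were 8.78% and 10.8% in Normal against 4.35% and 15.8% in Cstf2_KD (log2 fold change 0.05).

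**Figure D2:**
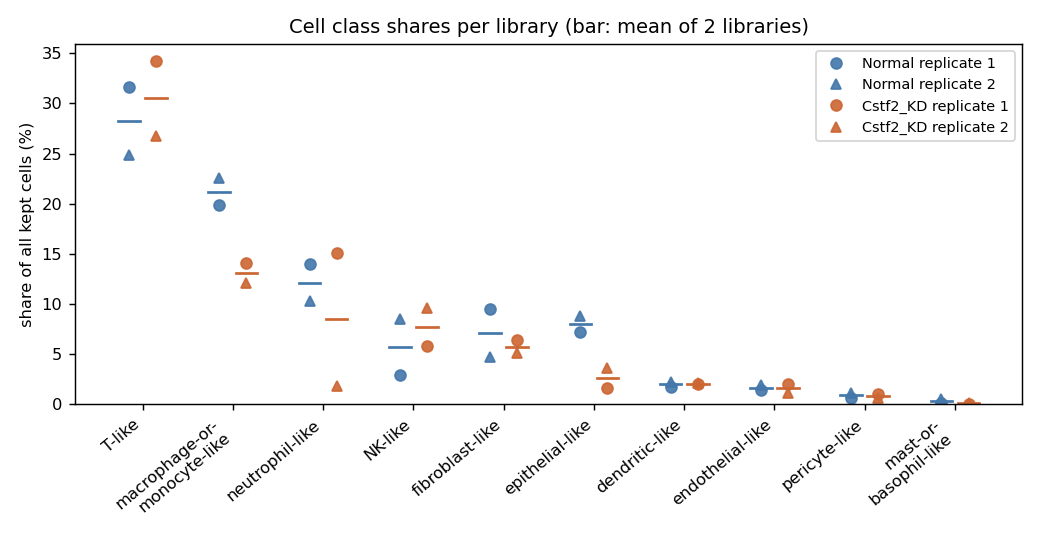
Share of all kept cells in percent (y axis) for each named class (x axis), with 1 point per library and bars at the mean of 2 libraries. Epithelial-like shares are 7.26% and 8.78% in Normal and 1.68% and 3.64% in Cstf2_KD, while neutrophil-like shares of the Cstf2_KD libraries lie apart at 15.1% and 1.88%.

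Immune cells were counted as those of the 6 named immune classes, without the unnamed clusters 9 and 19. Cluster 9, with markers of T and NK cells, held 6.77% and 6.65% of all kept Normal cells. In Cstf2_KD it held 9.48% and 9.20%, a difference that was not tested. Among immune cells, T-like cells made up 40.5% ± 6.36 in Normal and 49.4% ± 1.99 in Cstf2_KD (SD, n = 2; log2 fold change 0.29 ± 0.31). Macrophage-or-monocyte-like cells made up 30.5% ± 3.04 and 21.4% ± 2.31 (log2 fold change -0.51 ± 0.31). NK-like cells made up 8.22% ± 5.79 and 13.2% ± 7.13, and dendritic-like cells 2.88% ± 0.54 and 3.41% ± 0.79. None of the 6 immune classes passed the edgeR test (adjusted p = 0.638 for each), and none had an unadjusted p under 0.05. Without Cstf2_KD replicate 2 the NK-like and dendritic-like changes were -0.0032 and -0.02.

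Epithelial-like cells changed most in number of genes. Among the genes that rose were Fstl1, which encodes a secreted glycoprotein, from 9.88 ± 0.14 to 88.9 ± 11.1 CPM (SD, n = 2), Upp1, a uridine phosphorylase, from 42.1 ± 2.73 to 169 ± 18.3, and Uchl3, a ubiquitin hydrolase, from 20.9 ± 2.71 to 93.6 ± 10.0. Their log2 fold changes were 3.17 ± 0.15, 2.0 ± 0.14 and 2.16 ± 0.15. Ankrd1, a target of YAP signalling, rose by 2.20 ± 0.16. Among the genes that fell were Rnf128, an E3 ubiquitin ligase, with log2 fold change -2.48 ± 0.15, Smox, spermine oxidase, with -2.02 ± 0.14, complement component C3 with -2.00 ± 0.14, and Nrep with -2.54 ± 0.18. Adjusted p was 4.90e-04 for Fstl1, 6.78e-04 for Rnf128 and 8.34e-04 for the other 6. Of 13384 genes tested, 2158 rose and 2212 fell. DESeq2 called 2023 and 1812. The count was 2136 without Normal replicate 1 and 2404 without Normal replicate 2, and all 8 named genes still passed without any 1 library. C3 and Nrep went the other way in cluster 12 alone, with log2 fold changes of 0.88 and 0.36.

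The gene groups of the epithelial-like class were also followed in cluster 6 alone and in cluster 12, which is not part of the class. Clusters 16 and 22 were not tested alone. The clusters of the class were mixed differently in the groups. Cluster 16, led by cell cycle genes such as Ube2c, Cenpf, Top2a and Birc5, held 14 of 731 and 49 of 908 cells in Normal but 78 of 206 and 221 of 530 in Cstf2_KD. Of 27 cell cycle genes 25 rose (26 adjusted over the list alone), with a median log2 fold change of 1.84. Examples were the replication helicase subunit Mcm5, 2.41 ± 0.20, the mitotic ubiquitin-conjugating enzyme Ube2c, 2.28 ± 0.18, and Hmgb2, 1.83 ± 0.15. Of 20 replication-dependent histone genes 16 rose (16 adjusted over the list alone), among them Hist1h1d, 1.99 ± 0.17. Of 20 genes of MHC class I presentation 13 rose and 1, H2-T23, fell (14 and 1 adjusted over the list alone). The class I gene H2-Q7 rose by 1.97 ± 0.15, and the immunoproteasome subunits Psmb8 and Psmb10 by 2.05 ± 0.17 and 1.80 ± 0.15. Of 20 hypoxia and glycolysis genes 11 fell (12 adjusted over the list alone). The angiogenic factor Vegfa had -1.73 ± 0.16, the hypoxia-induced Ndrg1 -1.70 ± 0.15 and the glucose transporter Slc2a1 -1.27 ± 0.14. Of 22 oxidative phosphorylation genes 11 rose and 1, Uqcrh, fell (13 and 1 adjusted over the list alone), with Cox5b at 1.04 ± 0.14. Of 6 sex-linked genes, 4 genes of the Y chromosome rose (4 adjusted over the list alone), such as Eif2s3y from 0.62 ± 0.47 to 7.09 ± 1.82 CPM. Camera gave adjusted p = 1.13e-29 for the cell cycle, 1.51e-13 for histones, 4.23e-10 for MHC class I, 7.45e-09 for hypoxia, 0.00109 for oxidative phosphorylation and 0.0168 for the sex-linked list. Adjusted p = 0.99 for each of the 6 with an estimated correlation. In cluster 6 alone 8 of 27 cell cycle genes were higher, with a median of 0.50 (adjusted p = 0.0156, and adjusted p = 0.744 with an estimated correlation). Of 20 hypoxia genes there 10 were lower and 1 higher, with a median of -0.51 (adjusted p = 0.00533, and adjusted p = 0.661 with an estimated correlation). Hmgb2, Ube2c and Mki67 had 0.35 (adjusted p = 0.0504), 1.05 (0.137) and -0.00244 (0.998). In cluster 12 alone the lists of the cell cycle, histones and hypoxia did not pass, with medians of 0.00933, 0.59 and -0.0894 (adjusted p = 0.741, 0.0636 and 0.242), and Mcm5, Vegfa and Ndrg1 had -0.56, -0.25 and -0.00717. MHC class I presentation had 13 of 20 genes higher and 1 lower in cluster 6, with a median of 0.78 (adjusted p = 8.31e-13, and adjusted p = 0.661 with an estimated correlation). In cluster 12 it had 17 of 20 higher and a median of 0.75 (adjusted p = 2.63e-12, and adjusted p = 0.569 with an estimated correlation). Without Cstf2_KD replicate 1 the sex-linked list had an adjusted p of 0.154.

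Low Xist set a group of clusters apart. Xist, the RNA of the inactive X chromosome in female cells, was 35.2 to 99.6 raw CPM in clusters 3, 6, 12 and 16 and 558 to 1304 in every other cluster. The same 4 clusters had 345 to 575 raw CPM of the tumour suppressor gene Cdkn2a, against 5.67 to 46.6 elsewhere. Cluster 22 of the epithelial-like class was not among them, with 1304 raw CPM of Xist and 27.5 of Cdkn2a. The class thus mixed low-Xist and high-Xist cells. Cluster 22 held 0 of its 731 cells in Normal replicate 1 and 47 of 206 in Cstf2_KD replicate 1. The class without cluster 22 was not tested. With all libraries pooled, Ddx3y, a gene of the Y chromosome, had 3.11 to 53.1 raw CPM in clusters 3, 6, 12 and 16, against 0 to 1.67 elsewhere. Cluster 6 held little of it in the Normal libraries, with 0.813 and 1.45 raw CPM, within the range elsewhere. In the Cstf2_KD libraries cluster 6 had 13.5 and 10.3. In cluster 12 Ddx3y had 32.8 and 52.2 raw CPM in the Normal libraries and 62.8 and 52.3 in the Cstf2_KD libraries. Xist there was 62.0, 22.5, 26.6 and 21.7 in that order. The Y-linked Eif2s3y had 13.7 to 29.0, Uty 7.75 to 11.7 and Kdm5d 3.19 to 6.36. These values argue against an origin of cluster 12 cells in the animal of the high-Xist cells. For clusters 3, 6 and 16 the origin was not tested. Comparisons within the 4 clusters were added after the data were seen. In cluster 6 alone 1763 genes rose and 1580 fell, and in cluster 12 alone 1906 rose and 1639 fell. The changes of cluster 6 followed chromosomes: 8 of 19 autosomes had a median log2 fold change beyond all 1000 shuffles of genes over chromosomes, such as 0.49 on chromosome 14, 0.45 on chromosome 8 and -0.36 on chromosome 2. In cluster 12 there were 3 such autosomes, with -0.27 on chromosome 18, and in macrophage-or-monocyte-like cells 1.

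**Figure D3:**
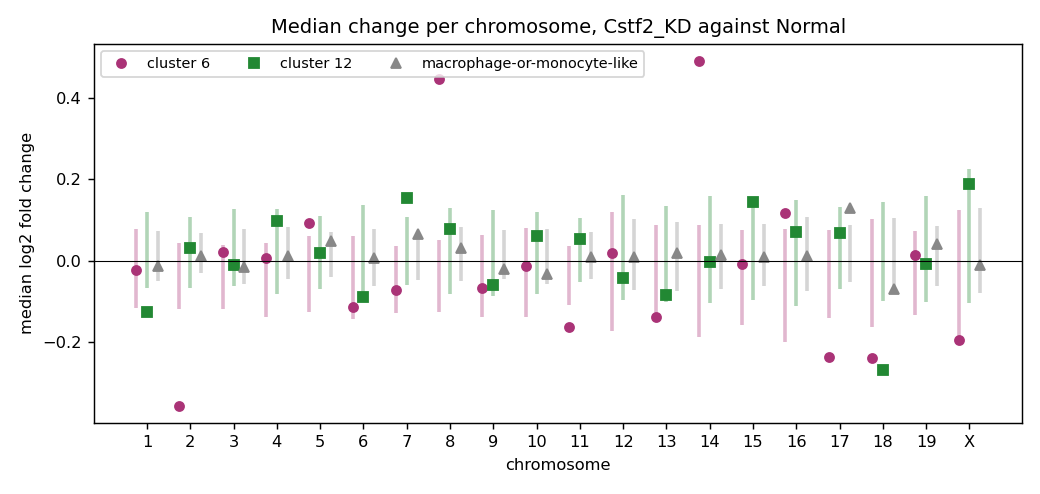
Median log2 fold change of Cstf2_KD against Normal (y axis) of the genes on each chromosome (x axis) in cluster 6, cluster 12 and macrophage-or-monocyte-like cells, with vertical lines for the range of 1000 shuffles of genes over chromosomes. In cluster 6 chromosomes 8 and 14 lie at 0.45 and 0.49, beyond their shuffles.

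**Figure D4:**
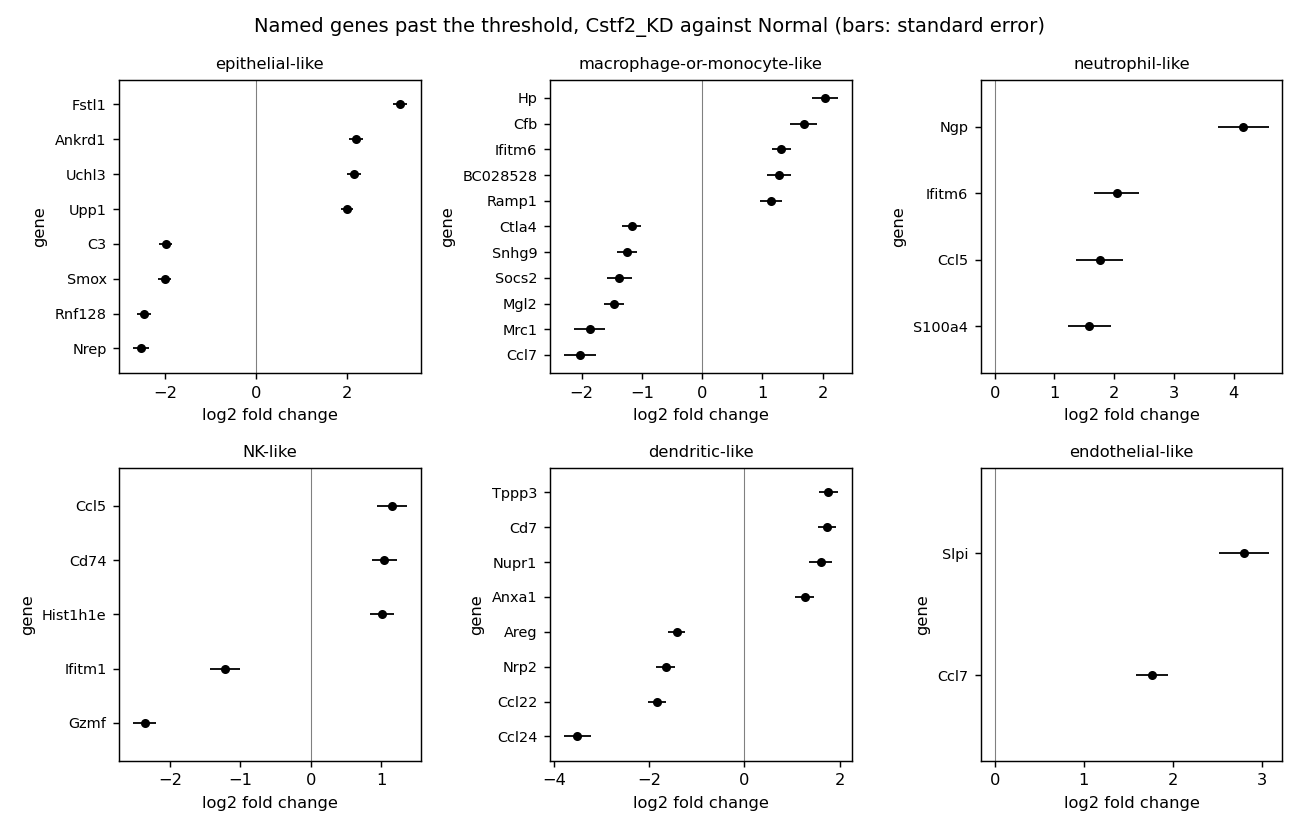
Log2 fold change of Cstf2_KD against Normal (x axis) with standard error bars for the named genes past the threshold (y axis), in panels by cell class. In epithelial-like cells values run from -2.54 for Nrep to 3.17 for Fstl1.

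The title of the series names CXCL10, a chemokine that draws T and NK cells through the receptor CXCR3, as does CXCL9. Cxcl10 (ENSMUSG00000034855) rose in epithelial-like cells, from 149 and 116 CPM in the Normal libraries to 376 and 665 in the Cstf2_KD libraries. The log2 fold change was 1.98 ± 0.33 (SE, n = 2 per group, adjusted p = 0.0144). With a replicate block this call ended, while Cxcl10 passed in macrophage-or-monocyte-like and neutrophil-like cells instead, as given with the processing below. In macrophage-or-monocyte-like cells Cxcl10 was 570 and 456 CPM in Normal and 1016 and 1065 in Cstf2_KD (1.02 ± 0.19, adjusted p = 0.0749). Dendritic-like cells had 0.84 ± 0.21 (adjusted p = 0.0538), fibroblast-like cells 0.99 ± 0.25 (0.836), T-like cells 0.73 ± 0.21 (0.494), neutrophil-like cells 1.12 ± 0.41 (0.474) and NK-like cells -0.22 ± 0.18 (0.686). Cxcl10 was higher in 8 of 9 classes and in both Cstf2_KD libraries in 7, passing over all genes in 1 class. A second adjustment took 20 rows alone, Cxcl9 and Cxcl10 in the 9 classes and in all cells summed. By it Cxcl10 passed in 6 classes. The summed rows hold the cells of the classes, so the 20 rows are not separate tests. All cells summed gave 0.96 ± 0.18, with adjusted p = 0.439 over all genes and 0.0108 over the 20 rows alone. Cxcl9 (ENSMUSG00000029417) rose in epithelial-like cells by 2.50 ± 0.40 (adjusted p = 0.0172, and 0.126 with per-cell marker classes). In NK-like cells it had 4, 23, 48 and 108 UMIs (2.05 ± 0.33, adjusted p = 0.00430). Free RNA there was put at 287% of these counts in Normal and 163% in Cstf2_KD, and the call ended at the finer clustering (0.286) and with per-cell marker classes (0.623). Cxcl9 was positive in all 9 classes, 0.02 in dendritic-like cells, with both Cstf2_KD libraries higher in 6, and passed in 6 when adjusted over the 20 rows alone. Free RNA was put at 9.02% of the epithelial-like Cxcl10 counts in the Cstf2_KD libraries and 42.5% of the Cxcl9 counts. No such share is given for Cxcl10 in the other classes, so free RNA may add to the count of classes. Without Normal replicate 2 the epithelial-like Cxcl10 change was 1.81 with an adjusted p of 0.0535, and the Cxcl9 call ended without either Normal library, with adjusted p of up to 0.208. The number of classes with Cxcl10 past the threshold was 2 or 3 without any 1 library. Both genes lie on the minus strand of chromosome 5 of GRCm38, Cxcl9 from 92321347 to 92328079 and Cxcl10 from 92346638 to 92348889.

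**Figure D5:**
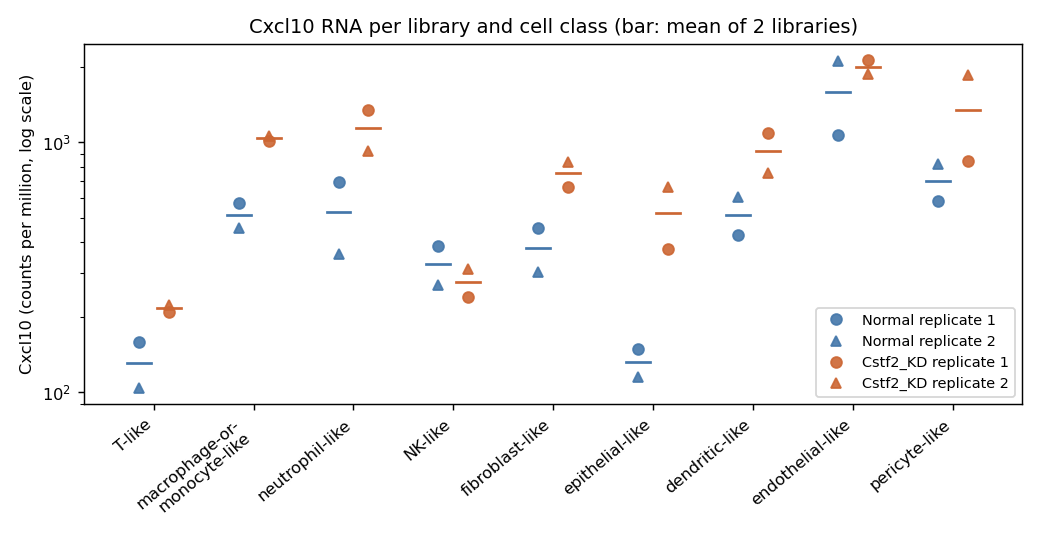
Cxcl10 CPM on a log scale (y axis) for each cell class (x axis), with 1 point per library and bars at the mean of 2 libraries. Both Cstf2_KD libraries lie above both Normal libraries in 7 of 9 classes, and in NK-like cells the groups overlap.

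In macrophage-or-monocyte-like cells the acute-phase gene Hp (haptoglobin) rose from 63.5 ± 17.1 to 261 ± 41.0 CPM (SD, n = 2; log2 fold change 2.04 ± 0.22, adjusted p = 0.0181). Ifitm6, an interferon-induced membrane protein gene of myeloid cells, rose by 1.32 ± 0.16, and Cfb, complement factor B, by 1.68 ± 0.22. Among the genes that fell, the C-type lectin Mgl2 had a log2 fold change of -1.47 ± 0.16 (adjusted p = 0.0181), the mannose receptor Mrc1 -1.87 ± 0.26 (0.0259) and the scavenger receptor Cd163 -4.06 ± 0.55 (0.0429). The monocyte chemoattractant Ccl7 fell by 2.03 ± 0.27 (adjusted p = 0.0297), and the platelet chemokine Ppbp had 19.5 ± 1.68 CPM in Normal and 0.51 ± 0.38 in Cstf2_KD. Of 11808 genes tested, 8 rose and 22 fell, and DESeq2 called 132 and 62. The class was mixed differently in the groups: cluster 1, led by Pf4, Mmp12 and C1qa, held 1437 and 1130 cells in Normal and 803 and 499 in Cstf2_KD, and cluster 0, led by Ifitm6 and Lyz2, held 122, 143, 252 and 352. In clusters 0, 1 and 2 alone, comparisons added after the data were seen, 8, 7 and 24 genes passed by edgeR. Ifitm6 passed in none of them (0.24, 0.43 and 0.60, adjusted p = 0.633, 0.760 and 0.696). Nor did Mrc1 (-0.61, -1.19 and -2.34, adjusted p = 0.528, 0.230 and 0.244) or Ccl7 (0.30, -1.92 and -1.77, adjusted p = 0.836, 0.0988 and 0.441). Cd163 was tested in cluster 1 only, where it had -5.97 (adjusted p = 0.143). Cfb passed in clusters 1 and 2 (adjusted p = 0.0440 and 0.0251), Hp and Mgl2 in cluster 2 (0.0205 and 0.0246) and Ppbp in cluster 1 (0.0158). Hp, Ifitm6, Cfb, Mgl2 and Ppbp passed without any 1 library, though Hp and Ifitm6 not at the finer clustering (adjusted p = 0.0893 and 0.0754). Mrc1 and Cd163 did not pass without Cstf2_KD replicate 1 (adjusted p = 0.0646 and 0.0758) or without Cstf2_KD replicate 2 (0.185 and 0.265), nor Ccl7 without the latter (0.144). The count was 189 without Normal replicate 1, 569 without Normal replicate 2, 84 without Cstf2_KD replicate 1 and 18 without Cstf2_KD replicate 2. It was 9 with doublets kept, where Mrc1, Cd163 and Ccl7 had adjusted p of 0.0564, 0.0589 and 0.0561.

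Genes known from regulatory T cells fell in the macrophage-or-monocyte-like class, 4 of 9 members (7 lower and 1 higher adjusted over the list alone). They were Il2ra, the high-affinity interleukin 2 receptor chain, with -1.72 ± 0.21, the cytokine Il10 with -1.51 ± 0.20, the costimulatory receptor Tnfrsf4 with -1.29 ± 0.17 and the checkpoint receptor Ctla4 with -1.17 ± 0.16. The list had an adjusted p of 3.96e-14 by camera and adjusted p = 0.284 with an estimated correlation. In cells of the class without a T cell marker UMI none of these 4 passed by edgeR, with log2 fold changes from -0.85 to -0.51. Within single clusters Il2ra passed in cluster 2 (-2.34, adjusted p = 0.0178), Ctla4 in cluster 2 (-1.39, 0.0313) and Il10 in cluster 1 (-2.50, 0.0329), while Tnfrsf4 passed in none. The list had medians of 0.0941, -0.77 and -1.37 in clusters 0, 1 and 2 (adjusted p = 0.628, 6.45e-07 and 9.64e-17, and adjusted p = 0.904, 0.315 and 0.387 with an estimated correlation). In the whole class without Cstf2_KD replicate 2 the adjusted p of the 4 genes lay between 0.0578 and 0.0846, with doublets kept between 0.148 and 0.466, and at the finer clustering between 0.0716 and 0.555. Of 36 interferon-stimulated genes none passed over all genes, while 11 were higher adjusted over the list alone and 35 were positive. The guanylate-binding proteins Gbp5 and Gbp2 had 0.86 ± 0.15 and 1.03 ± 0.24, and the list an adjusted p of 1.45e-11 (adjusted p = 0.284 with an estimated correlation). MHC class I presentation, 11 of 20 higher adjusted over the list alone and 0 over all genes, had 4.76e-08 (adjusted p = 0.585 with an estimated correlation). MHC class II presentation, 6 of 12 and 0, had 1.27e-05 (adjusted p = 0.585 with an estimated correlation). Suppressive myeloid genes had 3 of 16 lower, 7 adjusted over the list alone, and 2.88e-08 (adjusted p = 0.284 with an estimated correlation). Other chemokines had 2 of 19 lower, 7 lower and 1 higher adjusted over the list alone, and 5.17e-09 (adjusted p = 0.284 with an estimated correlation). A list of another cell type leaned lower. All 7 epithelial identity genes were lower, Krt8 by a log2 fold change of -1.17 ± 0.24 (adjusted p = 0.0819), none over all genes and 2 adjusted over the list alone, with a list p of 6.84e-05 (adjusted p = 0.284 with an estimated correlation). The 13 mitochondrially encoded genes were all higher, 7 adjusted over the list alone and 0 over all genes (1.99e-07, adjusted p = 0.284 with an estimated correlation).

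In dendritic-like cells Ccl24, a chemoattractant of eosinophils, fell from 72.4 ± 19.5 to 6.41 ± 1.74 CPM (SD, n = 2; log2 fold change -3.51 ± 0.29, adjusted p = 1.52e-06). Ccl24 and Arg1 were also among the 10 leading genes of macrophage-or-monocyte-like clusters 2 and 1. Ccl22, which draws regulatory T cells, had -1.84 ± 0.19 (3.39e-05), the epidermal growth factor receptor ligand Areg -1.42 ± 0.18 (2.07e-04) and Nrp2 -1.65 ± 0.19 (1.05e-04). Before doublets were removed, the finer clustering parted the class into a cluster led by Ccl22, Fscn1 and Ccr7, with 74 and 94 cells in Normal and 62 and 57 in Cstf2_KD, and a cluster led by Cd209a, with 144, 245, 235 and 288. Neither was tested alone. Cd7 rose by 1.74 ± 0.19 (6.34e-05), Tppp3 by 1.76 ± 0.20 (9.52e-05) and Anxa1, an annexin with anti-inflammatory activity, by 1.26 ± 0.19 (0.00147). Of 9520 genes, 66 rose and 80 fell, and DESeq2 called 56 and 48. Suppressive myeloid genes had 2 of 12 lower, Ccl22 and arginase Arg1, and 6 adjusted over the list alone (camera adjusted p = 2.92e-08, adjusted p = 0.676 with an estimated correlation). Genes of regulatory T cells had 1 of 9 lower and 4 adjusted over the list alone (2.94e-05, adjusted p = 0.751 with an estimated correlation). Cell cycle genes had 3 of 20 higher, Ccnb2, Stmn1 and Birc5, and 7 adjusted over the list alone (3.18e-04, adjusted p = 0.751 with an estimated correlation). With genes set aside for free RNA their median was -0.25. The collagen gene Col3a1, a fibroblast product, also rose, by 1.07 ± 0.21 (adjusted p = 0.0113, 0.0513 without Cstf2_KD replicate 2 and 0.0818 with per-cell marker classes). With those classes Cd7 had 0.73 (adjusted p = 0.146), Tppp3 0.89 (0.240), Areg -1.09 (0.0564), Ccnb2 2.33 (0.0660) and Ccl24 -3.69 (0.181), and at the finer clustering Ccl24 had -4.14 (0.154). The count of changed genes was 404 without Normal replicate 2, 287 without Normal replicate 1, 232 without Cstf2_KD replicate 1 and 76 without Cstf2_KD replicate 2.

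In NK-like cells the granzyme gene Gzmf fell from 269 ± 2.61 to 52.2 ± 0.17 CPM (SD, n = 2; log2 fold change -2.36 ± 0.17, adjusted p = 3.62e-10). Interferon-induced Ifitm1 fell by 1.22 ± 0.21 (adjusted p = 0.0203). The chemokine Ccl5 rose by 1.15 ± 0.21 (0.0173), Ccl3 by 0.87 ± 0.17 (0.0194) and Ccl4 by 0.85 ± 0.19 (0.0442). The MHC class II invariant chain Cd74 rose by 1.04 ± 0.17 (0.00536). Of 10091 genes, 19 rose and 8 fell, and DESeq2 called 14 and 0. Of 13 other chemokines 4 rose (the fourth was Cxcl12, a stromal product), 7 higher and 1 lower adjusted over the list alone (camera adjusted p = 5.51e-07, adjusted p = 0.538 with an estimated correlation). Collagens and matrix genes, which NK cells are not known for, had 1 of 22 higher and 7 adjusted over the list alone (2.94e-08, adjusted p = 0.538 with an estimated correlation). Without Normal replicate 2 these lists had adjusted p of 0.0952 and 0.0634. Of these Sparc rose by 0.92 ± 0.20 (adjusted p = 0.0402). With finer clusters or with per-cell marker classes 0 genes passed by edgeR. Normal replicate 1 held 292 NK-like cells. Ccl5 did not pass without either Cstf2_KD library (adjusted p = 0.163 and 0.453), Ccl3 without Normal replicate 2 (0.13), nor Ccl4 without Normal replicate 2 (0.101), Cstf2_KD replicate 1 (0.271) or Cstf2_KD replicate 2 (0.0678). Sparc did not pass without Normal replicate 2 (0.139) or Cstf2_KD replicate 2 (0.654). The count was 74 without Normal replicate 1, 156 without Normal replicate 2 and 147 without Cstf2_KD replicate 1.

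Neutrophil-like cells rose in Ngp, a granule protein gene of immature neutrophils, from 5.82 ± 0.07 to 99.9 ± 53.0 CPM (SD, n = 2; log2 fold change 4.16 ± 0.43, adjusted p = 1.04e-12). Ifitm6 rose by 2.04 ± 0.37 (9.63e-04) and the calcium-binding S100a4 by 1.58 ± 0.36 (0.0214). The chemokine Ccl5, a product of T and NK cells, rose by 1.76 ± 0.39 (0.0213). Of 7777 genes, 7 rose and 2 fell, and DESeq2 called 3 and 0. The 2 that fell, named after their values were seen, were Rab15 and Gm19951. Cytotoxic effectors, genes of T and NK cells, had 1 of 13 higher and 4 adjusted over the list alone (camera adjusted p = 4.36e-10, adjusted p = 0.581 with an estimated correlation). All 25 ribosomal protein genes were positive, 0 past the edgeR test over all genes or adjusted over the list alone (1.16e-10, adjusted p = 0.581 with an estimated correlation). All 12 mitochondrially encoded genes tested were positive, with a median of 0.85, 3 higher adjusted over the list alone and 0 over all genes (6.32e-10, adjusted p = 0.581 with an estimated correlation). Cstf2_KD replicate 2 held 274 of these cells. Ngp passed without any 1 library, while Ifitm6, Ccl5 and S100a4 had adjusted p of 0.394, 0.216 and 0.752 without Normal replicate 2, and of 0.0625, 0.817 and 0.653 without Normal replicate 1. Without Cstf2_KD replicate 2 Ccl5 and S100a4 had 0.111 and 0.0758. With doublets kept Ifitm6, Ccl5 and S100a4 had 0.103, 0.158 and 0.369, and with per-cell marker classes 0.0876, 0.366 and 0.995. The count was 22 without Normal replicate 1, 3 without Normal replicate 2, 20 without Cstf2_KD replicate 1 and 56 without Cstf2_KD replicate 2.

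T-like cells showed no gene past the edgeR threshold among 12787 tested, with 1210 at an unadjusted p under 0.05 and 17 called by DESeq2. Ifng, the cytokine interferon gamma that induces Cxcl9 and Cxcl10, was 354 and 308 CPM in Normal and 518 and 657 in Cstf2_KD (log2 fold change 0.83 ± 0.18, n = 2, adjusted p = 0.494 by edgeR). Ifng did pass with DESeq2 (adjusted p = 0.00755), without a filter on low counts (0.00258) and without Normal replicate 1 (0.0340). Klf2, a transcription factor of naive T cells, had 0.78 ± 0.16, the interleukin 33 receptor Il1rl1 -0.84 ± 0.20 and Tnfsf8 -0.63 ± 0.15 (adjusted p = 0.494 for each). Without a filter these 3 had adjusted p of 0.00350, 6.76e-04 and 0.0355. When each library was left out, Klf2 passed in 1 of the 4 fits and Il1rl1 in 2 (lowest adjusted p = 0.0229 and 0.00390). The cytotoxic protease Gzmb, 0.05 ± 0.58, and the checkpoint receptor Pdcd1, -0.04 ± 0.37, differed by less than the spread between replicates, while Gzmb was -0.57 without Normal replicate 1 (adjusted p = 0.592) and passed at 1.17 without Normal replicate 2 (0.00129). All 25 ribosomal protein genes were positive, with 0 past the test over all genes or adjusted over the list alone (camera adjusted p = 1.09e-09, adjusted p = 0.741 with an estimated correlation). Cytotoxic effectors had 2 of 16 higher adjusted over the list alone and 0 over all genes (5.67e-04, 0.176 without Normal replicate 1, adjusted p = 0.741 with an estimated correlation). Replication-dependent histones and cell cycle genes had medians of 0.62 and 0.32, with 0 of 20 and 0 of 27 past the test over all genes or adjusted over the list alone (9.64e-08 and 6.61e-07, adjusted p = 0.741 and adjusted p = 0.743 with an estimated correlation). Cluster 4, led by histone and cell cycle genes, held 185 of 3184 and 184 of 2571 T-like cells in Normal, and 275 of 4193 and 493 of 3893 in Cstf2_KD. Without Cstf2_KD replicate 2 the cell cycle list had an adjusted p of 0.0569. The number of genes past the threshold was 95 without Normal replicate 1, 244 without Normal replicate 2, 90 without Cstf2_KD replicate 1 and 5 without Cstf2_KD replicate 2.

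The makeup of T-like cells was compared at 1000 UMIs per cell. Cells with Cd8a or Cd8b1 and no Cd4 made up 41.1% ± 4.21 in Normal and 37.7% ± 0.04 in Cstf2_KD (SD, n = 2; log2 fold change -0.13 ± 0.23). Cells with Cd4 alone made up 10.0% ± 2.44 and 7.79% ± 0.76, and cells with Foxp3, the regulatory T cell factor, 2.28% ± 1.16 and 1.98% ± 0.20. None differed by edgeR (adjusted p = 0.645 for each, 0 with an unadjusted p under 0.05). As background, 0.331% to 2.19% of thinned epithelial-like cells had a CD8 UMI, at median depths before thinning of 16657 to 26500 UMIs against 3130 to 5344 in T-like cells. For Foxp3 this background was 0% to 0.189%, where 0 of 731 cells has an upper limit of 0.503%. Without thinning the CD8 shares were 52.7% and 53.6%, a log2 fold change of 0.02. The Cd4 shares were then 20.5% and 16.9%, and the Foxp3 shares 6.56% and 6.01% (log2 fold changes -0.28 and -0.12). All of these are shares of cells with a detected UMI, which fall with thinning, and not sizes of the subsets. Without Normal replicate 2 the CD8 change was -0.23 (adjusted p = 0.00905) and the Foxp3 change 0.43.

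Stromal cells showed few changes. In endothelial-like cells the protease inhibitor Slpi rose from 10.7 ± 5.26 to 71.6 ± 0.05 CPM (SD, n = 2; log2 fold change 2.80 ± 0.28) and Ccl7 rose by 1.77 ± 0.18 (adjusted p = 0.00857 for both). They were the 2 genes that passed of 10839, and DESeq2 called 17. In fibroblast-like cells 0 of 13159 genes passed by edgeR, with 651 at an unadjusted p under 0.05 and 28 called by DESeq2. There the lipid carrier Apoe had 1.38 ± 0.18 (adjusted p = 0.253) and integrin Itgb3 -1.25 ± 0.16 (0.253), and both passed with DESeq2 (6.53e-08 and 2.39e-04). In pericyte-like cells 0 of 8705 passed by edgeR, with 443 at an unadjusted p under 0.05 and 4 called by DESeq2. MHC class I presentation in fibroblast-like cells had 6 of 20 higher adjusted over the list alone and 0 over all genes (camera adjusted p = 8.80e-16, adjusted p = 0.402 with an estimated correlation). Cytotoxic effectors, which fibroblasts are not known to express, had 3 of 16 and 0 (4.63e-15, adjusted p = 0.402 with an estimated correlation). Cell cycle genes of endothelial-like cells had 4 of 27 lower adjusted over the list alone and 0 over all genes (3.95e-09, 0.497 with genes set aside for free RNA, adjusted p = 0.638 with an estimated correlation). Lists of fibroblast genes leaned higher in endothelial-like cells, by camera at the preset correlation only. Inflammatory fibroblast genes had 1 of 17 higher and 8 adjusted over the list alone (1.59e-18, adjusted p = 0.309 with an estimated correlation). Collagens and matrix genes had 0 of 22 and 5 (3.80e-12, adjusted p = 0.638 with an estimated correlation), with a median of 0.53, and of -0.0821 with genes set aside for free RNA. With per-cell marker classes Slpi and Ccl7 of endothelial-like cells had 0.65 (adjusted p = 0.840) and 1.03 (0.750). Ccl7 did not pass without Normal replicate 1 (0.522) or Normal replicate 2 (0.111). The number of genes past the threshold without 1 library ran from 1 (Normal replicate 1) to 181 (Cstf2_KD replicate 1) in endothelial-like, from 1 (Cstf2_KD replicate 1) to 48 (Normal replicate 2) in fibroblast-like and from 0 (Cstf2_KD replicate 2) to 190 (Normal replicate 2) in pericyte-like cells.

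Over the 9 classes, 254 list tests were made. With the preset correlation 110 passed, 83 higher and 27 lower. None passed with an estimated correlation (smallest adjusted p = 0.284) or with fry. Both rest on 2 residual degrees of freedom. In epithelial-like cells, where 4370 of 13384 genes passed, the smallest adjusted p by camera with an estimated correlation was 0.99. These checks could thus hardly be passed, and failing them does not show that a list was unchanged. The passes at the preset correlation stand without support from them.

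Whether the epithelial-like and macrophage-or-monocyte-like changes differed was tested directly. Of 13695 genes 1419 differed, with the fold change higher in epithelial-like cells for 818 and lower for 601. The Cxcl10 change was larger in epithelial-like cells by 0.93 ± 0.23 (adjusted p = 0.0413), and that of Cxcl9 by 1.62 ± 0.18 (adjusted p = 0.0043). For Cstf2 the difference of -0.31 ± 0.26 did not pass (adjusted p = 0.482). Without Normal replicate 1 only 1 gene differed. The number was 726 without Normal replicate 2, 1041 without Cstf2_KD replicate 1 and 616 without Cstf2_KD replicate 2, and the Cxcl10 difference passed only without Cstf2_KD replicate 1.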

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

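The tests on clusters, chromosomes and Ifng were chosen only after the result was seen, while those on free RNA and on T cell RNA in the same droplets were set before, except for the subtraction of free RNA from Cxcl10.

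The change between the groups differed between epithelial-like and macrophage-or-monocyte-like cells for 1419 of 13695 genes by the interaction test. Differences are given as epithelial-like minus macrophage-or-monocyte-like log2 fold change. They were 1.62 for Cxcl9, 0.93 for Cxcl10, 3.14 for Fstl1, 2.39 for Uchl3 and 0.95 for Upp1. They were -2.19 for Rnf128, -1.95 for Smox, -2.66 for C3 and -2.06 for Nrep. Cfb differed by -1.98 and Ramp1 by -2.49, both of which rose in macrophage-or-monocyte-like cells, although Ramp1 passed in none of the clusters 0, 1 and 2 of that class alone. Ctla4 differed by 1.42 and Ccl7 by 1.01, both of which fell there. Without Normal replicate 1 only 1 gene differed. Of the 13 named genes, Cxcl9, Cfb, Ramp1, Fstl1, Uchl3, Rnf128, Smox and C3 still passed when any other single library was left out, while Cxcl10, Ccl7, Upp1 and Nrep passed in 1 of the 4 such fits and Ctla4 in none.

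In epithelial-like cells 4370 genes differed between the groups, against 146 in dendritic-like cells, the next highest class. Different clusters making up the class would leave few changed genes in each, but 3343 genes differed in cluster 6 alone, which argues against this as the whole account. In cluster 6 the shifts were those that tumour cell populations with other chromosome numbers predict. There 8 of 19 autosomes had a median beyond all 1000 shuffles, against 1 in macrophage-or-monocyte-like cells. Ddx3y there was 0.813 and 1.45 raw CPM in Normal and 13.5 and 10.3 in Cstf2_KD. Vmn2r7 had 273 and 406 UMIs in Normal and 0 and 0 in Cstf2_KD. The 3343 genes of cluster 6 therefore cannot be assigned to the knockdown. In cluster 12 the largest median, on chromosome 18, was 0.27 in size, with no other autosome over 0.25, so that such populations and an effect of the knockdown on 3545 genes cannot be told apart there. The knockdown itself was not tested against tumour origin, since each group held its own tissue, and may act beside it.

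Cxcl10 was higher in epithelial-like cells of both Cstf2_KD libraries, and free RNA in the droplets was put at 9.02% of its Cstf2_KD counts, under the 10% set beforehand but close to it, and at 17.9% in Cstf2_KD replicate 1 alone, so that the same bound applied to each library, a rule tried after the values were seen and then replaced, leaves free RNA open. After subtracting it, 116 and 96.8 raw CPM were left in Normal and 379 and 647 in Cstf2_KD, over 2-fold for each pair of libraries, a rule put in its place after the result was seen, which argues against free RNA as the whole account. Genes of chromosome 5, which carries Cxcl10, had medians of 0.0921 in cluster 6, 0.0180 in cluster 12 and 0.142 in the epithelial-like class. The first and last lay beyond all shuffles, so chromosome 5 was shifted there. The Cxcl10 changes were 2.18, 1.68 and 1.98 in that order, which argues against the dosage of that whole chromosome as the whole account. Tumour cell populations that differ in other chromosomes cannot be told apart from the knockdown, since Cxcl10 was higher in cluster 12 (adjusted p = 0.00274) but chromosome 18 was shifted there, and indirect effects were not tested. More Ifng RNA in T-like cells could contribute and stays open, with a log2 fold change of 0.83 (95% interval 0.41 to 1.25) and adjusted p of 0.494 with edgeR and 0.00755 with DESeq2.

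Genes of regulatory T cells were lower in macrophage-or-monocyte-like cells. In cells of the class without a T cell marker UMI the median over 8 members was -0.56 instead of -1.23, or 46.0% of it, which is consistent with T cell RNA in the same droplets as part of the account. There the calls ended with smaller changes and wider errors, as for Il2ra with -0.68 ± 0.40 after -1.72 ± 0.21. Free RNA was put at 18.2% of the list's counts in the Normal libraries, between the 10% and 50% set beforehand. A share in that range decided nothing by that rule. The share was no lower in the Cstf2_KD libraries, so the fall was not confined to the free RNA part. This argues against free RNA as the whole account for the list's pooled counts, while a part stays open. A change in myeloid cells also stays open, as Il10 had -0.85 ± 0.24 in cells without a T cell marker UMI (edgeR adjusted p = 0.153). Il10 passed in cluster 1 alone (-2.50, adjusted p = 0.0329) and Il2ra and Ctla4 in cluster 2 alone (-2.34 and -1.39, adjusted p = 0.0178 and 0.0313). Those fits kept the cells with a T cell marker UMI, so they cannot tell T cell RNA from a myeloid change.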

How the results depend on the processing

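The values here are those that turned direction in another setting, and those answering a comparison that moved across the threshold. Over all settings, 314 values that answer a comparison and 2254 of single genes and lists kept their direction and their side of the threshold, and 67 and 136 passed it only in another setting. Another 27 and 300 no longer passed it, and 27 and 35 turned direction. The clusters taken alone or together, the cells without a T cell marker UMI and the crossed pairs were chosen after seeing the data. Without 1 library, 1 residual degree of freedom is left instead of 2, and the lone library is assumed to vary like the others. Leaving out free RNA genes was not run for all cells together, class shares or T cell subsets, and a class absent under another naming gave no value there. Where a value moved, the cause was not tested, except that fewer libraries, cells or genes were used by construction. Depth and the spread between libraries limit the calls and were not separated. Of 100 genes changed 2-fold in simulated counts, 27 were recovered in epithelial-like, 8 in neutrophil-like and 25 in pericyte-like cells, with biological coefficients of variation of 0.215, 0.246 and 0.169, against 61 in NK-like cells with 0.120. The interaction test recovered 14.

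Cells kept per Normal library went from 10209 to 9059 with stricter cells, 9979 with at most 10% mitochondrial UMIs and 10840 with doublets kept, and per Cstf2_KD library from 13401 to 11740 with stricter cells.

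Class shares turned direction without passing the threshold. At the finer clustering the log2 fold change was -0.0647 for dendritic-like (main 0.0398) and 0.60 for fibroblast-like cells (main -0.31), and -0.0584 for dendritic-like cells among immune cells (main 0.24). The finer fibroblast-like class took in a cluster led by Spp1, Grem1 and Mgp. Before doublets were removed it held 41 and 67 cells in Normal and 310 and 1441 in Cstf2_KD. Spp1, Grem1 and Mgp were also among the leading genes of the unnamed cluster 12 of the main clustering. With classes named per cell it was 0.48 for fibroblast-like, 0.11 for endothelial-like (main -0.04) and 0.17 for pericyte-like cells (main -0.04), and with TMM over the classes it was 0.0982, 0.38 and 0.40. With the Xist-low clusters together the epithelial share had 0.0451 (main -1.59). The CD8 share of T-like cells had 0.0239 without thinning (main -0.13). Leaving out each library gave -0.13 to 0.23 for dendritic-like, -0.13 to 1.42 for NK-like, -0.72 to 0.27 for fibroblast-like, -0.0769 to 0.30 for T-like, -2.34 to 0.12 for mast-or-basophil-like, -0.51 to 0.32 for endothelial-like, -0.40 to 0.36 for pericyte-like and -2.69 to 0.31 for neutrophil-like cells. Among immune cells it gave -2.38 to 0.42 for mast-or-basophil-like, -2.28 to 0.28 for neutrophil-like, -0.0174 to 0.46 for dendritic-like and -0.00323 to 1.68 for NK-like cells. The CD8 share ranged from -0.23 to -0.0173, past the threshold without Normal replicate 2 (adjusted p = 0.00905), and the Foxp3 share from -0.65 to 0.43.

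Counts of changed genes moved in many settings. Leaving out free RNA genes also cut the genes tested. These went from 11808 to 1903 in macrophage-or-monocyte-like, from 7777 to 1416 in neutrophil-like and from 10091 to 3900 in NK-like cells. They went from 9520 to 4404 in dendritic-like and from 10839 to 3534 in endothelial-like cells. A lower count in that setting therefore does not show that the calls came from free RNA. For T-like cells 0 became 2 with classes named per cell, 230 without a filter, 17 with DESeq2 and 5 to 244 with each library left out. For macrophage-or-monocyte-like cells 30 became 9 with doublets kept, 815 without a filter, 194 with DESeq2, 9 with free RNA genes left out, 8 in cluster 0 alone, 7 in cluster 1 alone and 18 to 569 with each library left out. For neutrophil-like cells 9 became 21 with at most 10% mitochondrial UMIs, 1 with doublets kept, 1 with classes named per cell, 17 without a filter, 3 with DESeq2, 1 with free RNA genes left out and 3 to 56 with each library left out. For NK-like cells 27 became 0 at the finer clustering, 0 with classes named per cell, 71 without a filter, 14 with DESeq2, 16 with free RNA genes left out and 32 to 156 with each library left out. For fibroblast-like cells 0 became 20 without a filter, 28 with DESeq2 and 1 to 48 with each library left out. For dendritic-like cells 146 became 273 at the finer clustering, 402 without a filter, 347 with free RNA genes left out and 76 to 404 with each library left out. For endothelial-like cells 2 became 4 with doublets kept, 0 with classes named per cell, 187 without a filter, 17 with DESeq2, 0 with free RNA genes left out and 1 to 181 with each library left out. For pericyte-like cells 0 became 6 with doublets kept, 3 with classes named per cell, 76 without a filter, 4 with DESeq2 and 0 to 190 with each library left out. For epithelial-like cells 4370 became 2136 to 4283 with each library left out.

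Cstf2 passed in 1 class and in 0 with free RNA genes left out, where it was not tested in epithelial-like cells. Cxcl10 passed in 1 class, in 2 with stricter cells, with at most 10% mitochondrial UMIs, with doublets kept and at the finer clustering, in 5 without a filter, in 4 with DESeq2 and in 2 to 3 with each library left out. In all kept cells Cxcl10 had 0.97 with DESeq2 (adjusted p = 1.9e-04, main 0.96), and Cxcl9 0.54 to 1.08 with each library left out (main 0.83). Lists past the threshold went from 110 of 254 to 39 of the 110 that could still be tested with free RNA genes left out, to 0 with an estimated correlation and to 0 with fry. Genes that differed between classes went from 1419 to between 1 and 1041 with each library left out.

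Single genes turned direction as well. In cluster 12 alone C3 had 0.88, Nrep 0.36, Mcm5 -0.56, Hmgb2 -0.14, Hist1h1d -0.0485 and the cell cycle list 0.00933, and Nrep had 0.41 in the Xist-low clusters together. Cxcl10 in NK-like cells had 0.0557 at the finer clustering, 0.11 with classes named per cell and -0.48 to 0.0387 with each library left out. Cxcl9 in dendritic-like cells had -0.61 with classes named per cell, -0.0366 with free RNA genes left out and -0.40 to 0.68 with each library left out. In macrophage-or-monocyte-like cells of cluster 0 alone Cstf2 had 0.15, Ccl7 0.30, Il2ra 0.0844, Il10 0.50, the regulatory T cell list 0.0941 and the other chemokines list 0.15. Cav1 in fibroblast-like cells had 0.21 at the finer clustering, where the class took in the cluster led by Spp1 and Grem1, and 0.0470 with classes named per cell. With free RNA genes left out the cell cycle list had -0.25 in dendritic-like cells and the collagens list -0.0821 in endothelial-like cells. With each library left out, T-like cells had -0.19 to 0.10 for Cd8a, -0.52 to 0.0149 for Cd4, -0.59 to 0.49 for Foxp3, -0.57 to 1.17 for Gzmb and -0.44 to 0.52 for Pdcd1. Cstf2 in fibroblast-like cells had -0.19 to 0.18, Cxcl10 in endothelial-like cells -0.0791 to 0.91 and Cxcl9 in pericyte-like cells -1.13 to 2.0.

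No label says whether same-numbered libraries share an origin, so it is unknown whether the replicate numbers pair them. The main tests treat all libraries as unpaired. Same-numbered libraries had correlations of their deviations of 0.28 in T-like, 0.04 in macrophage-or-monocyte-like, 0.24 in neutrophil-like, 0.12 in NK-like, 0.28 in fibroblast-like, 0.08 in dendritic-like, 0.03 in endothelial-like, -0.08 in pericyte-like and -0.49 in epithelial-like cells. With a replicate block the counts were 1130 for T-like, 255 for macrophage-or-monocyte-like, 31 for neutrophil-like, 866 for NK-like, 189 for fibroblast-like, 310 for dendritic-like, 30 for endothelial-like and 4319 for epithelial-like cells, and Cxcl10 passed in 2 classes, macrophage-or-monocyte-like (adjusted p = 0.0218) and neutrophil-like cells (0.0412), but no longer in epithelial-like cells (1.93, adjusted p = 0.0703). Ifng in T-like cells passed with the block (0.0326). With crossed pairs 3646 genes passed in epithelial-like cells, against 4370 without pairs. Crossed pairs were not run in the other classes, so pairing stays open there.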

Other observations

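The Xist and Y chromosome comparisons, the genes given for both clusters and Vmn2r7 were chosen only after the data were seen.

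In the pooled clusters 6, 12 and 16, which had low Xist, genes of the Y chromosome differed between the groups. Ddx3y, a Y-linked RNA helicase, had 5.24 and 11.5 raw CPM in the Normal libraries and 46.6 and 41.7 in the Cstf2_KD libraries (log2 fold change 2.35 ± 0.36, edgeR adjusted p = 0.00821). Eif2s3y, a Y-linked translation factor, had 2.96 ± 0.20 (adjusted p = 1.56e-04). In cluster 6 alone Ddx3y had 3.31 ± 0.35 (adjusted p = 2.94e-04) and Eif2s3y 3.79 ± 0.47 (6.74e-04). In cluster 12 alone Eif2s3y had 1.14 ± 0.17 (adjusted p = 0.00105), while Ddx3y, with 0.52 ± 0.21, did not pass (0.103). The changes of the 2 clusters were not tested against each other. The clusters were mixed differently in the groups: cluster 6 held 717 and 827 of the 884 and 1116 Normal cells, and 81 and 305 of the 533 and 2303 Cstf2_KD cells. Krt8, a keratin gene of epithelium, thus had -1.19 ± 0.10 in the 3 clusters together (adjusted p = 3.66e-04), but 0.42 ± 0.14 in cluster 6 (0.0454) and -0.31 ± 0.13 in cluster 12 (0.0887). Vmn2r7, a vomeronasal receptor gene, had 289 and 457 UMIs in these clusters of the Normal libraries and 0 and 0 in the Cstf2_KD libraries.

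Some genes passed in both clusters, though both comparisons use the same 4 libraries. Rnf128 fell by 1.52 ± 0.14 in cluster 6 and by 1.83 ± 0.23 in cluster 12, and Smox by 1.36 ± 0.13 and 1.33 ± 0.19. Psmb8 rose by 1.91 ± 0.13 and 1.48 ± 0.12, and Fstl1 by 2.16 ± 0.17 and 1.88 ± 0.13. Cstf2 itself fell by 0.75 ± 0.18 in cluster 6 (adjusted p = 0.0133), less than in cluster 12, where it fell by 2.61 ± 0.24, a difference that was not tested.

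Cluster 3 had low Xist as well, with a median of 691 to 1068 UMIs per library. It held 2.09% and 5.06% of the Normal cells and 4.28% and 14.6% of the Cstf2_KD cells. Cluster 9, led by Trdc, Tcrg-C4 and Klra genes, carried markers of T and NK cells alike, and cluster 19, led by Igkc, Ighm and Jchain, those of B and plasma cells.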
